A study of Drosophila melanogaster with 3 samples.

How the data were processed

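Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster embryos of 0 to 24 h that express jigr1 fused to eGFP, with an antibody against GFP. Chromatin was sonicated to fragments of 200 to 800 bp. The 3 samples are biological replicates of 1 group, so the labels imply no contrast between groups, and replicates are named here by the number the labels give them. An input or other control sample is not analysed here.

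The files used are peak lists on the dm6 assembly. Each replicate has a ranked list, which holds every peak that the authors' irreproducible discovery rate (IDR) step ranked, and a thresholded list. In the deposited lists the signal is the peak caller's signal value against the control within that list, so it was compared between replicates only by rank. The deposited score is a scaled IDR in whole numbers up to 1000; in the ranked lists it followed minus 125 times the log2 of the IDR within 1 for 100% of peaks. The thresholded lists began at a score of 830, which is an IDR of 0.01. The aligner, the peak caller and their versions are not given in the sources used here. The lists hold no read counts, so the sequencing depth is unknown. The whole series has 4 further thresholded lists, of 1168, 2350, 868 and 1701 peaks, 1 of which the authors call conservative. These were used as alternatives, and the conservative list also to count its regions that no replicate's list holds. The ranked lists of the whole series were not used.

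Gene models came from the Ensembl annotation of BDGP6.54, release 115, and sequence from the RefSeq copy of the same assembly; 0 peaks ended past the end of an arm. The analysis was restricted to the 7 chromosome arms 2L, 2R, 3L, 3R, 4, X and Y, with 18277 genes, 13968 of them protein-coding. Coordinates are counted from 1. A consensus region was made by merging peaks of the thresholded lists that shared at least 1 bp and keeping those to which at least 2 of 3 replicates contributed. Its summit is the mean of the summits of the strongest peak of each contributing replicate. Its strength is the mean, over those replicates, of the percentile of its signal within the replicate's list. A summit within 500 bp of a transcription start site (TSS) of any gene was called a promoter, and other summits are called distal.

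Overlap between lists was tested with 1000 circular shifts of 1 list along its arms, one-sided, and correlation of signal across shared regions with 100000 permutations of the pairings. The promoter share was tested against 10000 random placements on the same arm, two-sided. The X share used an exact binomial test against the X share of the length of arms 2L, 2R, 3L, 3R, 4 and X. Divergent promoters, those with a TSS of a gene on the other strand within 1000 bp upstream, were compared as an odds ratio between genes with a region at a promoter and the other protein-coding genes. A summit between 2 TSSs counts for both genes, so the share was set against 1000 draws of random genes with regions at the observed offsets from a TSS, two-sided, and counted again with the nearest TSS only. Promoter and distal strength were compared with 100000 permutations. Motifs and 8-mers, each with its reverse complement, were counted in windows reaching 100 bp to either side of the summit, and in windows of the same width centred 500 bp to 1 side, chosen at random. The counts were compared with an exact McNemar test, two-sided, with Benjamini-Hochberg adjustment over the 20 motifs or over the 8-mers seen in 10 or more windows. 8-mers were discovered on arms 2L, 2R and X and tested again on 3L, 3R and 4. Peaks within 50 kb of jigr1 were compared with 10000 random windows of the same size on the same arm, one-sided.

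Gene lists were tested with Fisher's exact test, two-sided, adjusted over the 28 lists with members, for genes with a consensus summit within 500 bp of a TSS. The background was all protein-coding genes on the arms, or all genes there for classes given by biotype. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, proteasome subunits, oxidative phosphorylation, spliceosome, translation factors and tRNA synthetases, cell cycle and DNA replication, Polycomb and Trithorax group, insulator and promoter architectural proteins, the MADF-BESS family, segmentation, homeotic genes and cofactors, neuroblasts and neural precursors, neuronal differentiation, glia, the Notch pathway, the tracheal system, muscle, germline, haemocytes and fat body, histones, heat shock proteins, abundant cytoskeletal and glycolytic genes, cuticle, chorion and yolk, chemoreceptors, transfer RNA genes, snRNA genes, snoRNA genes and microRNA genes. The microRNA list had 0 members by biotype and was rebuilt by symbol after the annotation was seen. The comparisons, lists, motifs, thresholds and the rule for naming genes were fixed before the data were examined. That rule names the genes at the 25 strongest consensus regions called in 3 of 3 replicates, up to 4 bound members of each list past the threshold, the 5 8-mers with the smallest p in discovery, and jigr1, jing, mir-92a, mir-92b, ph-d and ph-p whatever their values. An adjusted p under 0.05 counts as called.

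Intervals are exact 95% binomial intervals (Clopper-Pearson) and cover counting error only; with 3 replicates the SD over replicates is given beside them. The tests were checked on simulated data of similar size, for gene lists with the 25 lists that are not RNA classes. With nothing planted, 1 of 400 motif tests, 2 of 500 list tests, 1 of 20 promoter tests and 1 of 20 X tests passed. Simulated regions were placed evenly along the arms, and bound genes were drawn independently of each other. A base content that differs between summit and flank, and genes that share a region, were therefore not simulated. The motif and list rates need not hold for data with these features. A motif planted in 10% of windows was called in 20 of 20 runs, and an odds ratio of 4 planted in the 73 mitochondrial ribosomal protein genes was called in 156 of 200 runs.

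Alternatives were the omission of each replicate in turn, regions called in 3 of 3 replicates, the whole-series lists, a score of 1000, a signal of 30 or more, summits within 100 bp in place of overlap, TSS windows of 200 and 1000 bp, the nearest TSS only, protein-coding TSSs, other backgrounds for the promoter and X shares, matched promoters and shuffled windows for motifs, a summit window reaching 50 bp to either side, 6-mers, and a window of 20 kb around jigr1. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Peaks on scaffolds outside the arms were left out of the comparisons because the annotation used here gives no position on an arm for them.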

Results

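Binding of jigr1, a protein with a MADF DNA-binding domain whose gene hosts the microRNA genes mir-92a and mir-92b, was profiled in embryos of 0 to 24 h in 3 biological replicates. The thresholded lists held 926 peaks in replicate 1, 1359 in replicate 2 and 943 in replicate 3, a mean of 1076 ± 245 (SD, n = 3). On the chromosome arms these came to 865, 1305 and 913 peaks. The ranked lists held 105458, 103085 and 89411 peaks. Median peak width was 304, 320 and 324 bp, and the median signal value was 65.1, 64.9 and 64.0.

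The first comparison asked whether the same regions recurred between replicates. The strongest region called in 3 of 3 replicates lay at the promoter of Ugalt, which encodes the UDP-galactose transporter (X 2703731 to 2704037, signal values 579, 697 and 331). Of the 865 regions of replicate 1, 84.9% overlapped a peak of replicate 2 and 52.8% a peak of replicate 3. Of the 1305 regions of replicate 2, 42.6% overlapped a peak of replicate 3. The reverse shares, which depend on the length of the lists, were 55.8% of replicate 2 in replicate 1, 51.4% of replicate 3 in replicate 1 and 61.8% of replicate 3 in replicate 2. Shifted lists gave a mean of 0.559%, 0.393% and 0.402% for these pairs in the first direction (circular-shift permutation test, one-sided, p = 0.000999 for each pair and after adjustment over the 3 pairs, the smallest the 1000 shifts can give). Across shared regions, Spearman's rho of the signal was 0.815 for replicates 1 and 2 over 717 regions, 0.680 for replicates 1 and 3 over 453 regions and 0.630 for replicates 2 and 3 over 548 regions (two-sided permutation p = 1e-05 for each, raw and adjusted over the 3 pairs, the smallest the permutations can give). Regions within a genome are not independent replicates.

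Merging the lists gave 1718 regions, of which 438 were called in 3 of 3 replicates, 404 in 2 and 876 in 1. The 842 regions called in at least 2 replicates are the consensus, with a median width of 341 bp and 298 kb in all. Replicates 1 and 2 shared 279 regions that replicate 3 lacked, whereas replicates 1 and 3 shared only 15 that replicate 2 lacked. Replicate 2 alone held 453 regions and replicate 3 alone 309.

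**Figure D1:**
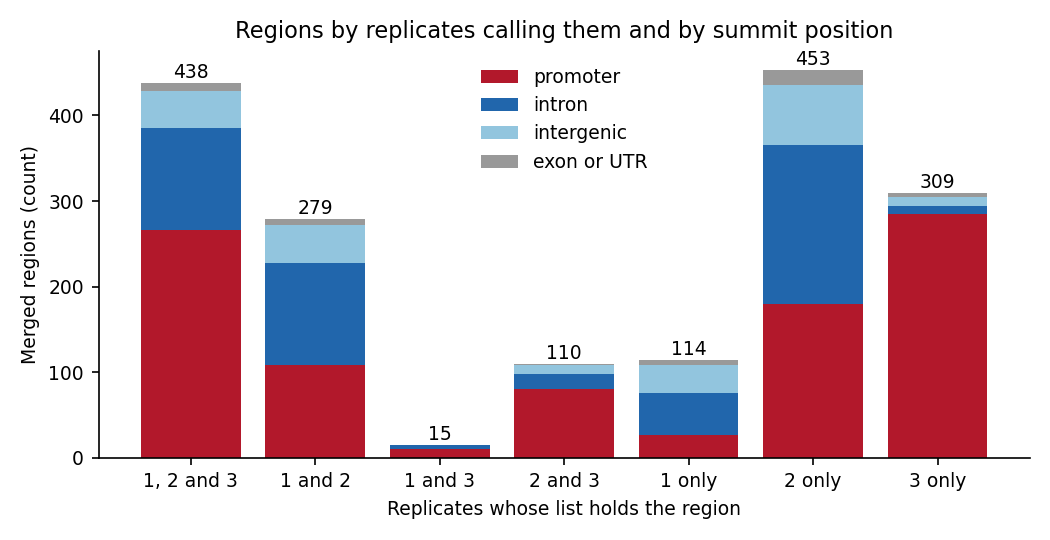
Number of merged regions (vertical axis, count) by the replicates whose lists hold them (horizontal axis), stacked by the position of the summit. The 438 regions in all 3 lists are 60.7% promoter, the 279 of replicates 1 and 2 are 39.1% promoter and the 309 of replicate 3 alone are 92.2% promoter.

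The second comparison asked where jigr1-eGFP regions lay. Among the 25 strongest regions called in all 3 replicates, 18 lay at promoters, 4 in introns and 3 elsewhere, and 8 lay at promoters of more than 1 gene. After Ugalt came the promoter of CG14100 (3L 19590478 to 19590757, signal values 455, 558 and 278) and a promoter of ph-p, which encodes the Polycomb group protein polyhomeotic (X 2137218 to 2137480, 411, 479 and 266). The next was an intron of Adf1, which encodes another MADF-domain transcription factor, 769 bp from its nearest TSS (2R 6662920 to 6663207, 460, 612 and 213). Chromatin genes among the 25 were Chro, which encodes the chromodomain protein Chromator, at a promoter shared with the TFIIH subunit gene Ssl1 (3L 22878768 to 22879029, 318, 452 and 245), and the overlapping HMG-box genes HmgZ and HmgD, with a region in an intron (2R 21703235 to 21703612, 391, 532 and 196). Mitochondrial genes were mRpL41, mRpS10, mRpS23, PNPase and CIA30, a complex I assembly factor gene that shares its region with CG7601.

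The other promoters among the 25 strongest were those of Tcs5 and CHMP2B, CG5611 and Mtl, Art3 beside mRpS10, CenG1A beside mRpS23, px, Shc and Atat, CG18549, Fkbp14, GstE13, CG31145, lncRNA:CR44619 and, beside mRpL41, lncRNA:CR44463. The other introns were those of CG11050 and of the nested genes Hr3, CG12912 and CG46321, of which Hr3 encodes a nuclear receptor of the ecdysone response. The 3 regions elsewhere had CG13323, lncRNA:CR45643 and lncRNA:CR45695 as their nearest genes, 11923, 890 and 8385 bp from a TSS. Over all 25 regions, signal values ran from 175 to 579 in replicate 1, from 230 to 697 in replicate 2 and from 147 to 373 in replicate 3.

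Over the consensus, 466 of 842 summits lay at promoters, 55.3% (95% interval 51.9 to 58.7) against 13.6% for random placement, a 4.08-fold difference (permutation of placements, two-sided, p = 0.0002, the smallest the 10000 draws can give). Introns held 260 summits (30.9% against 39.6% of the arms) and intergenic sequence 98 (11.6% against 27.0%). Coding exons, 13.1% of the arms, held 0 of 842 summits, and 3' UTRs held 3. In the replicates' own lists coding exons held 5 of 865, 11 of 1305 and 3 of 913 summits (0.578%, 0.843% and 0.329%, a mean of 0.583% ± 0.257, SD, n = 3). By replicate, the promoter share was 48.9% in replicate 1, 49.8% in replicate 2 and 74.4% in replicate 3, a mean of 57.7% ± 14.4 (SD, n = 3). Regions called in replicate 3 alone lay at promoters in 285 of 309 cases (92.2%), against 266 of 438 (60.7%) for regions of all 3 replicates and 109 of 279 (39.1%) for those of replicates 1 and 2 alone. Both differences passed Fisher's exact test, two-sided (p = 3.38e-24 and p = 1.9e-08), in a comparison chosen after the lists were seen.

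**Figure D2:**
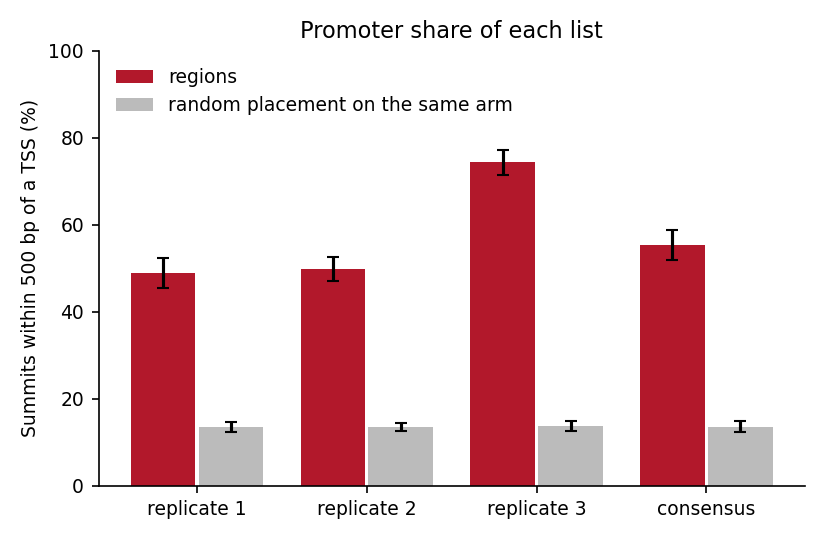
Share of summits within 500 bp of a TSS (vertical axis, %) in each replicate's list and in the consensus, with exact 95% intervals, beside the mean share for random placement on the same arm, with its SD. The lists stand at 48.9%, 49.8%, 74.4% and 55.3%, all above the 13.5% to 13.7% of random placement.

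Genes with a region at a promoter numbered 646 of the 13968 protein-coding genes (4.62%). Many sat head to head with a neighbour, as Tcs5 and CHMP2B, CG7601 and CIA30, Art3 and mRpS10, and Atat and Shc did. Of the 646 genes, 456 (70.6%, 95% interval 66.9 to 74.1) had a divergent promoter, against 5071 of the other 13322 (38.1%), an odds ratio of 3.91. The share was 66.0%, 70.5% and 70.8% by replicate, a mean of 69.1% ± 2.70 (SD, n = 3). A summit between a divergent pair counts for both genes, which raises the odds ratio without any preference. Random genes given regions at the same offsets from a TSS had a mean share of 52.7% and a mean odds ratio of 1.75 (permutation of genes, two-sided, p = 0.002, the smallest the 1000 draws can give). With only the nearest TSS counted, 248 of 430 genes (57.7%, 95% interval 52.8 to 62.4) had a divergent promoter, an odds ratio of 2.13, against 38.9% and 0.975 for the random genes (permutation p = 0.002, again the smallest). Both comparisons were added after the data were seen.

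Promoter regions ranked higher in signal than distal ones. The mean percentile was 59.8 at promoters and 53.0 elsewhere, a difference of 6.83 (permutation test, two-sided, p = 2e-05). By replicate the differences were 11.0, 10.1 and 3.70, a mean of 8.27 ± 3.98 (SD, n = 3), and that of replicate 3 did not pass (permutation p = 0.0881).

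The X chromosome held 180 of the 840 consensus regions on the arms other than Y, 21.4% (95% interval 18.7 to 24.4), against 17.6% of the length (exact binomial test, two-sided, p = 0.00426). The regions at Ugalt and ph-p were among them. The share was 22.9% in replicate 1, 21.8% in replicate 2 and 15.9% in replicate 3 (exact binomial p = 0.192 in replicate 3), a mean of 20.2% ± 3.76 (SD, n = 3). The call was lost without replicate 1 (18.98%, exact binomial p = 0.4), without replicate 2 (20.97%, exact binomial p = 0.0639) and for regions of 3 of 3 replicates (20.5%, exact binomial p = 0.103). Arm 4 held 1 region and Y held 2.

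The next comparison asked which sequences lay under the summits. Summits were rich in A and T. The G and C content was 34.2% within 100 bp of consensus summits and 44.0% in the flanks, and by replicate it was 34.8% ± 0.784 against 44.0% ± 0.561 (SD, n = 3). The contrast was 32.9% against 45.9% at promoters and 35.7% against 42.2% at distal regions. Of the 20 fixed motifs, 3 were called. The TATA box lay in 88 summit windows (10.5%) and 32 flanks (3.80%), with an adjusted exact p of 8.31e-07. CA repeats lay in 15 summit windows and 67 flanks (adjusted exact p = 2e-08), and GA repeats, the site of Trl, in 21 and 48 (adjusted exact p = 0.00599). By replicate the TATA box was at 9.43% ± 0.465 of summits and 3.84% ± 1.30 of flanks (SD, n = 3).

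The GA repeat difference of -3.21 percentage points was -2.37 without replicate 1 (adjusted exact p = 0.234), -1.10 without replicate 2 (adjusted exact p = 0.888) and -2.05 for regions of 3 of 3 replicates (adjusted exact p = 0.454).

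These calls did not stand against other backgrounds. Against promoters without a region, at the same offset from the TSS, 0 of 20 motifs were called by Fisher's exact test, with 2 at an unadjusted p under 0.05, and the TATA box stood at 10.9% against 6.65% (adjusted p = 0.275). Against the same windows shuffled with their dinucleotide counts kept, a test added after the data were seen, the TATA box stood at 88 windows against a mean of 78.1 (permutation test, two-sided, adjusted p = 0.433). In that test CA and GA repeats turned to higher counts than in shuffled windows, and the DRE, the site of DREF, had 14 windows against 2.55. The core of BEAF-32 sites had 82 against 51.5, Motif 1, the site of M1BP, 7 against 1.57, and Motif 7 31 against 10.01, each at an adjusted permutation p of 0.00444. Against flanks, the other motifs named here did not pass, with adjusted p of 0.394 for the DRE, 0.114 for the BEAF-32 core and for Motif 7, and 1 for Motif 1. The BEAF-32 core was called against flanks without replicate 2 and for regions of 3 of 3 replicates.

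In discovery, 149 of 4715 8-mers were called over 492 regions, 124 higher and 25 lower at summits than in flanks. Of the 124, 59 held no G or C. On the 348 regions of the other arms, 144 of the 149 had the same direction and 90 passed again. The 5 with the smallest p were AATATATT, ATATTTTA, AAAAATTT, ATTTAAAA and TTAAATAA, and the first 4 were among the 90. TTAAATAA passed on the other arms when adjusted over the 5 alone (adjusted exact p = 0.0357) but not over the 149 (adjusted exact p = 0.0566), and its call over the 5 was lost without replicate 2 (adjusted exact p = 0.0923) and without replicate 3 (adjusted exact p = 0.0784). ATTTAAAA lay in 14.4% of summit windows and 3.74% of flanks there (adjusted exact p = 6.21e-06), and AATATATT in 8.33% and 1.44% (adjusted exact p = 3.22e-05). Against shuffled windows AATATATT stayed higher, with 67 windows against a mean of 21.9, whereas AAAAATTT did not (84 against 96.3). These counts are over all arms, so they include the regions from which the 8-mers were picked.

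**Figure D3:**
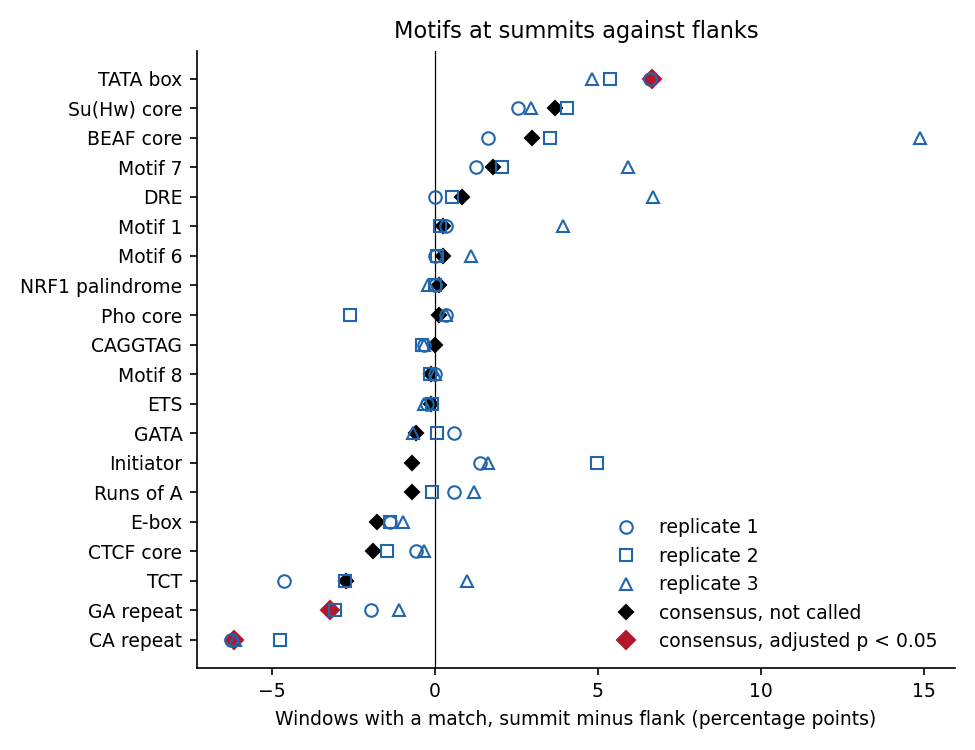
Share of summit windows with a match minus the share of flanks (horizontal axis, percentage points) for the 20 fixed motifs (vertical axis), with diamonds for the consensus and open symbols for each replicate. The TATA box is higher by 6.65 points and CA and GA repeats are lower; the BEAF-32 core and the DRE of replicate 3 lie apart from those of replicates 1 and 2.

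The gene lists asked which groups of genes had a region at a promoter. Of 28 lists, 7 were called, 3 with more bound genes than the background and 4 with fewer. The mitochondrial ribosomal protein genes had regions at 9 of 73 members (12.3%, odds ratio 2.93, Fisher's exact test, adjusted p = 0.0381), led by mRpL41, mRpS10, mRpS23 and mRpL23, which were bound in 3 of 3 replicates. With each region counted only for the gene of its nearest TSS, 4 of the 73 were bound and the call was lost (odds ratio 1.83, exact test, adjusted p = 0.577). Of the insulator and promoter architectural protein genes, 4 of 19 were bound (21.1%, odds ratio 5.53, exact test, adjusted p = 0.0403): Chro, Cp190, Trl and lola. Of the MADF-BESS family, which shares jigr1's DNA-binding domain, 3 of 10 were bound (30%, odds ratio 8.87, exact test, adjusted p = 0.0403): brwl, jigr1 itself and hng3. By replicate, the bound share of these lists was 14.2% ± 5.54, 24.6% ± 3.04 and 30% ± 17.3 (SD, n = 3). Replicate 3 had 1 bound member of the MADF-BESS family and replicates 1 and 2 had 4 each, and the family had 1 of 10 bound without replicate 1 (odds ratio 3.08, exact test, adjusted p = 0.761) or without replicate 2 (odds ratio 4.10, exact test, adjusted p = 0.731). With 2 bound it was not called, for a TSS window of 200 bp (exact test, adjusted p = 0.149) and a score of 1000 (adjusted p = 0.194). This list is a chosen set of symbols that includes the tagged gene.

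Groups with fewer bound genes were histone genes with 0 of 118 (Fisher's exact test, adjusted p = 0.0381), chemoreceptor genes with 0 of 179, transfer RNA genes with 1 of 290 and snoRNA genes with 1 of 269 (adjusted p = 0.00543 for each of the latter 3). The bound members were tRNA:Tyr-GTA-1-8 and snoRNA:Psi18S-920. Each gene copy counted as an independent gene in these tests. Whether peaks could be called at genes in many similar copies, such as histone and transfer RNA genes, was not tested. A low count there may therefore not mean absent binding. MicroRNA genes, listed by symbol after the data were seen, had 0 of 260 (exact test, adjusted p = 0.00271 as a further list). The TSS of a gene here is the 5' end of its annotated transcript. For an RNA gene inside a host gene, such as mir-92a in jigr1, transcription need not start there. A region at the host's promoter can then be missed, as that in jigr1 was for mir-92a, 553 bp away. Low counts of microRNA and snoRNA genes may therefore not mean absent binding at their promoters. By replicate the bound share of histone genes was 0.282% ± 0.489, of chemoreceptor genes 0.186% ± 0.323, of transfer RNA genes 0.575% ± 0.718 and of snoRNA genes 0.372% ± 0.372 (SD, n = 3). Without replicate 2, and with regions of 3 of 3 replicates, 0 of the 28 lists were called by Fisher's exact test, with 5 at an unadjusted p under 0.05 in each. Without replicate 1, 3 lists were called, those of mitochondrial ribosomal protein, chemoreceptor and transfer RNA genes. Without replicate 3, 5 lists were called, the 7 less those of mitochondrial ribosomal protein and histone genes.

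The other 21 lists did not pass. Among genes of basic cell functions, regions lay at 4 of 85 cytosolic ribosomal protein genes, 0 of 48 proteasome genes, 4 of 84 oxidative phosphorylation genes, 1 of 29 spliceosome genes and 6 of 83 genes of translation factors and tRNA synthetases. They also lay at 3 of 48 cell cycle and DNA replication genes, 1 of 19 heat shock protein genes, 2 of 22 abundant cytoskeletal and glycolytic genes and 0 of 32 snRNA genes. Among genes of chromatin and development, they lay at 4 of 36 Polycomb and Trithorax group genes (ph-p, brm, E(z) and Trl, exact test, adjusted p = 0.259), 3 of 24 Notch pathway genes (gro, aph-1 and E(spl)m3-HLH, adjusted p = 0.272) and 2 of 14 glial genes (moody and Gli, adjusted p = 0.343). Neuroblast genes had 1 of 29 (numb), neuronal differentiation genes 1 of 29 (elav) and muscle genes 2 of 25 (Msp300 and sls). Segmentation genes had 0 of 27, homeotic genes 0 of 12, tracheal genes 0 of 18, germline genes 0 of 13, and haemocyte and fat body genes 0 of 18. The cuticle, chorion and yolk list had 1 bound gene (0.813% of its members, exact test, adjusted p = 0.166). Its bound member was Cp190, an insulator gene that the list's name pattern took in.

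**Figure D4:**
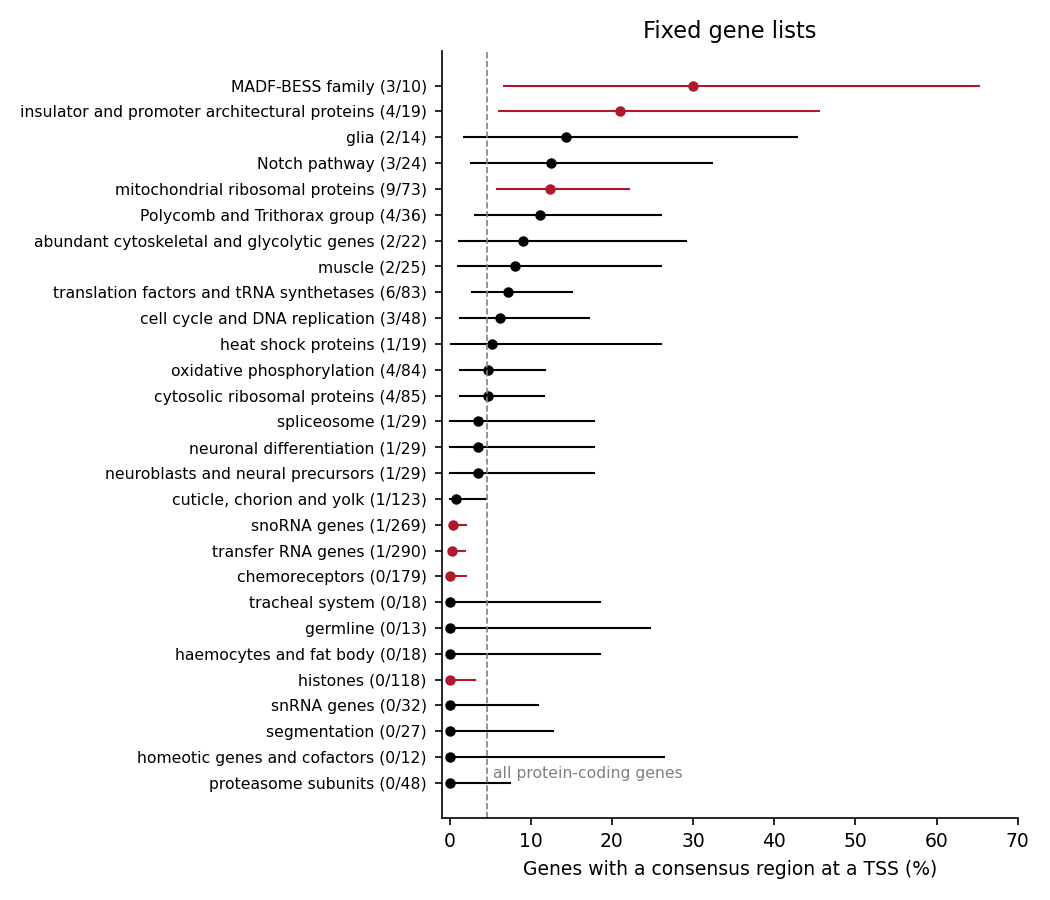
Share of each list's genes with a consensus region within 500 bp of a TSS (horizontal axis, %), with exact 95% intervals; bound and total members stand in brackets and called lists are red. The dashed line is the 4.62% of all protein-coding genes, and the called lists run from 0% for histones and chemoreceptors to 30% for the MADF-BESS family.

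The last comparison looked at jigr1's own locus and at loci fixed in advance. A region lay inside jigr1, its summit 187 bp from 1 of the gene's TSSs and 553 bp from the 5' end of mir-92a (3R 25646881 to 25647229), in replicates 1 and 2 with signal values of 58.1 and 119 and not in replicate 3. Within 50 kb of jigr1 there were 4 consensus regions, against a mean of 0.634 in random windows (random-window permutation test, one-sided, p = 0.0163). The other 3 lay 4385 bp from a TSS of Ssadh, at the promoters of RASSF8 and Tnks, and at those of Idh3g and CG4743. The replicates had 3, 5 and 2 peaks in this window (permutation p = 0.0391, 0.013 and 0.197), a mean of 3.33 ± 1.53 (SD, n = 3). Without replicate 1 the window held 2 regions (permutation p = 0.084), without replicate 2 it held 1 (permutation p = 0.235), and 1 region was called in 3 of 3 replicates (permutation p = 0.223). The labels do not say whether the transgene adds a copy of this locus, which could raise the signal here without more binding. The random windows were not matched for the number of promoters.

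The ph-p gene held 3 consensus regions, and the 1 nearest to a TSS lay 476 bp from it in all 3 replicates (X 2137743 to 2138066, signal values 180, 242 and 156). Its neighbour ph-d had no region inside, and the nearest lay 813 bp from its TSS, in replicates 1 and 2 (signal values 112 and 114). The jing gene held 0 consensus regions and 1 peak of replicate 2. The consensus region nearest to a TSS of jing was that in Adf1, 49271 bp away, and the region nearest to the 5' end of mir-92b was that in jigr1, 4339 bp away.

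**Figure D5:**
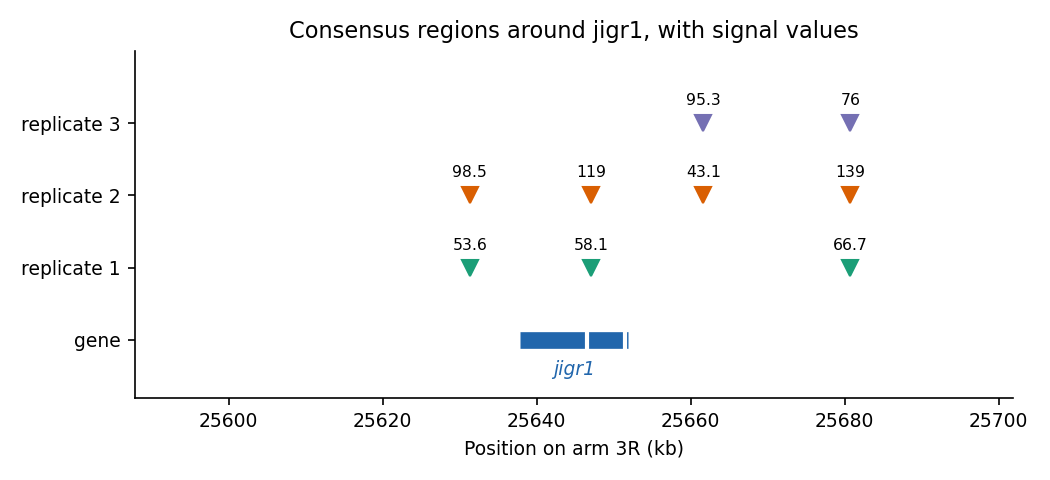
Consensus regions within 50 kb of jigr1 along arm 3R (horizontal axis, kb), with a triangle and the signal value in the row of each replicate that called the region; the blue bar is jigr1 and the white marks in it are mir-92a and mir-92b. Of the 4 regions, the 1 in jigr1 has values of 58.1 and 119 in replicates 1 and 2.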

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

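The tests of abundant transcripts, of near misses in replicate 3, of distal against promoter regions on X, of repeats and of the regions left out by the authors were chosen after the results they bear on were seen, as was every comparison between combinations of replicates; the other tests were set before their results were seen. The labels give 1 group, so no biological explanation was tested for the patterns weighed in this part.

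Peaks outside the comparisons formed 3 kinds. On scaffolds that are not part of the 7 arms there were 61 peaks in replicate 1, 54 in replicate 2 and 30 in replicate 3, and 100% of them in each replicate lay on scaffolds assigned to the X chromosome without a position. Peaks that reach a score of 830 in the ranked list but are missing from the thresholded list numbered 147 in replicate 1, 152 in replicate 2 and 48 in replicate 3, with signal values up to 1217, 1229 and 332. The highest values in the thresholded lists were 579, 697 and 373. Off the arms lay 80, 68 and 26 of the missing peaks. Why they were left out is not given, so binding sites cannot be told apart here from sites excluded as unreliable. Of the sites left out, 12 on the arms were shared by all 3 replicates. The strongest was an intron of ush, a GATA cofactor gene (2L 480932 to 481234, signal values 511, 711 and 332), which would rank at 2, 1 and 2 in the lists. Others lay in introns of Lk6 (193, 254 and 190), tara (163, 169 and 128) and trx, a Trithorax group gene (110, 168 and 114), and at the promoters of larp (202, 270 and 130), cbt (89.4, 123.5 and 77.1) and the pair pont and Sirt6 (109, 125 and 73.8). In the authors' conservative list of the whole series, 365 of 1605 regions overlapped no replicate's list, and 24.9% of these lay at promoters.

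Replicate 3 differed from replicates 1 and 2 in where its regions lay. Depth of the lists below the strongest peaks is argued against, since among the 500 strongest peaks replicate 3 stood 16.6 percentage points above the higher of the others (76.6% against 60.0% and 55.2%). Near misses in replicates 1 and 2 are argued against for most of the added promoters, since the best ranked peak at the 285 promoter regions of replicate 3 alone had a median percentile of 0 in replicate 1 and 44.2 in replicate 2, with regions lacking a ranked peak counted as 0, although the upper quartile in replicate 2 was 95.5. Near misses in replicate 3 stay open for the distal regions it lacked: at the 170 called in replicates 1 and 2 alone its best ranked peak had a median percentile of 97.4, and adding all 279 regions of replicates 1 and 2 alone would put its promoter share at 66.1%. Genes with abundant transcripts stay open. The cytosolic ribosomal protein and abundant cytoskeletal and glycolytic genes together had an odds ratio of 4.73 for a region of replicate 3 alone. These were 13 of 107 genes (Fisher's exact test, two-sided, p = 1.36e-05) and 3.19% of the genes with such a region. The odds ratio was above 1 for spliceosome (8.81), translation factor and tRNA synthetase (3.11) and oxidative phosphorylation genes (3.06). It was also above 1 for mitochondrial ribosomal protein (2.47), proteasome (2.23) and snRNA genes (1.35). Of these lists only that of the spliceosome was called. The odds ratio was 0.434 for transfer RNA, 0.154 for snoRNA, 0.283 for histone and 0 for heat shock protein genes, none of them called. Transcript levels were not measured, so the lists cannot decide how many of the regions this covers.

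The excess of regions on the X chromosome lay among distal regions, with 102 of 374 on X (27.3%) against 78 of 466 promoter regions (16.7%, Fisher's exact test, two-sided, p = 0.000264). Easier peak calling on X is argued against, since ranked peaks that do not pass had a mean X share of 16.2% ± 0.773 (SD, n = 3), under the 17.6% of length. The regions left out by the authors are argued against, since the share with them put back was 22.6%. Copies of a long repeat are argued against too, since the share was 21.3% without the 5 regions on transposable elements. Besides, 0 regions shared a stretch of 50 bp or more with another, and shorter shared stretches were not counted. The call was lost without replicate 1 and without replicate 2, with shares of 18.98% and 20.97% that still lay above the length share, and replicate 3 by itself stood at 15.9%.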

How the results depend on the processing

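Of 275 alternative values, 198 kept their result, 55 kept their direction and lost the call, 19 moved and 3 reversed. A test kept its result if its direction and its side of the threshold held. A count kept its result if it stayed within a fixed ratio of the main value, and moved otherwise. That ratio is not a spread over replicates: 106 8-mers without replicate 3, against 149, counted as kept. The promoter share (35.5% to 67.6%) and the difference in strength (5.33 to 13.9 percentile points) kept their calls in all alternatives run. The odds ratio of divergent promoters (2.13 to 5.73) kept its direction and was lowest with the nearest TSS only; the other alternatives count both genes of a pair and were not set against random genes. A score of 1000, a signal of 30 or more, shuffled windows, the microRNA list by symbol and the nearest TSS for divergent promoters were added after the data were seen. The planned limit of an IDR of 0.01 moved nothing, since the lists stop there, and gives no value.

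Leaving out each replicate in turn gave 453 to 717 consensus regions, an X share of 18.98% to 22.5%, 53 to 106 8-mers, 0 to 5 gene lists and 1 to 3 regions near jigr1. Requiring 3 of 3 replicates gave 438 regions, an X share of 20.5%, 5 motifs, 41 8-mers, 0 gene lists and 1 region near jigr1; both choices leave fewer regions to test. The conservative list gave 1605 regions and 5 motifs, and the narrow summit window 5 motifs. Matched promoters gave 0 motifs and shuffled windows 10, with GA repeats at 1.85 and CA repeats at 1.23 percentage points above the shuffles and AAAAATTT at -1.46. Of 6-mers 533 were called, from another number of tests. TSS windows of 200 bp gave 4 gene lists, the whole-series list of 868 peaks 3 and a score of 1000 3. Those of 1000 bp gave 5, without the mitochondrial ribosomal and insulator lists (Fisher's exact test, adjusted p = 0.0616 for each). Over 14 alternatives the call was lost in 8 for mitochondrial ribosomal protein genes, 8 for insulator genes and 9 for the MADF-BESS family. Except where regions or tests were fewer, the cause was not tested. No read counts were used, so the part of depth in the differences between lists is unknown.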

Other observations

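Every comparison here was chosen after the data were seen, except the test of initiators at distal regions, which was set before its result was seen.

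Summits at promoters lay upstream of the nearest TSS in 406 of 466 regions (87.1%), at a median offset of -142 bp with quartiles of -223 and -97 bp. Between divergent genes the geometry favours that side, so the test was run where no TSS of the other strand lay within 1000 bp upstream. There 225 of 253 summits lay upstream (88.9%, exact binomial test, two-sided, p = 2.12e-39). The promoters called in replicate 3 alone carried other sequences than those called in all 3 replicates. The BEAF-32 core lay in 43.5% of the former and 13.5% of the latter (Fisher's exact test, two-sided, adjusted p = 9.15e-14), the DRE in 16.5% and 3.38% (adjusted p = 1.69e-06), Motif 1 in 9.12% and 0.376% (adjusted p = 2.22e-06) and Motif 7 in 14.4% and 3.76% (adjusted p = 6.53e-05). The other 16 motifs did not pass. TATA boxes stood at 8.77% and 10.2%.

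Gene lists were tested in each combination of replicates against the background, not between combinations. Regions of replicate 3 alone lay at 6 of 29 spliceosome genes, U2af38 and SmB among them (odds ratio 8.81, Fisher's exact test, two-sided, adjusted p = 0.00444), and at 5 of 22 abundant cytoskeletal and glycolytic genes, betaTub56D, Gapdh2, Pgk, eEF2 and eEF1alpha1 (odds ratio 9.91, adjusted p = 0.00501). They also lay at 8 of 85 cytosolic ribosomal protein genes, RpS2 and RpL28 among them (odds ratio 3.51, exact test, adjusted p = 0.0308). Regions of replicates 1 and 2 alone lay at 3 of 10 MADF-BESS genes, brwl, hng3 and the tagged gene jigr1 itself (odds ratio 40.5, exact test, adjusted p = 0.00378). A further region at brwl was called in all 3 replicates.

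The 8-mer CACTGAGA, picked outside the naming rule, is 1 of 8 called higher with 4 or more G or C. All 8 hold CACTG on 1 strand or the other, so they may be forms of 1 sequence and are not separate findings. Another, CACAGTGG, lay at 20 summits and 3 flanks on arms 3L, 3R and 4 (exact McNemar test, two-sided, adjusted p = 0.00143). The others were not examined for position. CACTGAGA lay within 150 bp of the summit in 49 of 842 consensus regions, in 33 of 376 distal ones (8.78%) and 16 of 466 promoters (3.43%, Fisher's exact test, two-sided, p = 0.00161). It read towards the summit in 46 of 51 matches (exact binomial test, two-sided, p = 2.33e-09), from a median distance of 81.5 bp. On arms 3L, 3R and 4, which took no part in its discovery, it did so in 15 of 19 matches (exact binomial p = 0.0192), and windows reaching 100 bp held it at 14 summits and 2 flanks (exact McNemar test, two-sided, adjusted p = 0.0093). Regions with it lay in introns of ush, aop, Psc, which encodes a Polycomb group protein, ImpL2, pnt and edl and at the promoter of numb. By replicate, 4.62%, 3.91% and 2.96% of windows reaching 100 bp from the summit held it, against 0.347%, 0.690% and 0.438% of windows centred 500 bp to 1 side.

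Base composition is argued against for this 8-mer, since on arms 3L, 3R and 4 windows shuffled with their dinucleotide counts kept held it in a mean of 0.83 windows against 14 observed (two-sided permutation p = 0.002, the smallest the 1000 shuffles can give). Copies of a long repeat are argued against for the 49 regions. Of these, 0% overlapped a transposable element or shared a stretch of 50 bp or more with another of them. Shorter shared stretches were not counted, so copies of a short or diverged repeat stay open. Both regions in introns of babos, for example, shared further bases on either side of the 8-mer. Its reverse complement holds TCAGT but then a G, whereas the initiator TCAGTY ends in C or T, so it holds only part of an initiator. It might still mark start sites, but 0% of the 16 matches at promoters had an annotated TSS of that strand within 20 bp (exact 95% upper limit 20.6%). Whether the 8-mer marks start sites that the annotation lacks at distal regions was not decided. TCAGTY matches at distal regions without the 8-mer pointed away from the summit in 48.9% of 88 cases (exact 95% interval 38.1 to 59.8). The same share at promoters, where start sites are annotated, was 54.9%. The 8-mer is not a TCAGTY match, so these shares cannot bear on it.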
